A study of Helianthus annuus with 12 samples.

How the data were processed

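Leaf RNA of 2 sunflower lines, B728 and C6, was sequenced in 12 libraries, 3 from each of 4 groups: mock-inoculated control and infected leaves, the latter collected 24 h after inoculation. Groups and replicate numbers were taken from the labels. Per the labels' protocols, messenger RNA was captured with poly-T beads and libraries were made with an Illumina kit from NEB. Per the submitters' processing notes the tools included HISAT2, an aligner, and DESeq2; their versions, the genome build and the counting step are not given in the sources used here. Whether counting used strand is not given either, so reads of overlapping or antisense genes, and of near-identical copies, cannot be separated and such genes are uncertain.

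Per the file headers, each deposited file holds 1 library with a raw count and an FPKM value per gene. The deposited counts were whole numbers, and the main tests used them as they stand. The deposited FPKM values, scaled by the authors for depth and gene length, served for alternatives. Each file has 27359 genes, all in the same order. Every gene had an FPKM of at least 1 in at least 3 libraries, so 0 genes failed that filter, and how the genes were chosen is not stated. The headers use 1 code per group, C728 for B728 control, T728 for B728 infected, C6 for C6 control and T6 for C6 infected libraries, each beside the treatment; here the labels' names were followed, and C6 means the line.

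Of the genes, 22858 carry a LOC symbol and 4501 (16.5%) are newGene loci with no symbol. Symbols were looked up in a table of sunflower genes on the assembly HanXRQr2.0, which may differ from the authors' build, so none of its coordinates are given and its positions served only to tell which genes neighbour each other. It matched 22349 symbols, of which 22203 are protein coding. The table has no product descriptions. The 48 gene lists fixed before the data were examined were defined on such descriptions, so 0 could be filled and no gene list test was run. For the same reason no function is given for any gene. The rule for named genes, also fixed before, took genes by fold change among those with a description; its provision for identifiers without one took at most 2 genes higher and 2 lower per comparison, by the smallest adjusted p. A gene named in one comparison is also given in others.

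Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter by group (1 gene removed, 27358 tested) and a quasi-likelihood fit with 1 mean per group over all 12 libraries, which leaves 8 residual degrees of freedom. The common biological coefficient of variation was 23.9%. The comparisons were the infection response in each line, the difference of these responses, and the difference between the lines without and after infection. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F. CPM values use TMM-scaled library sizes, except those of loci read in 1 line and of the carry-over estimate, which use total counts. A floor of 3 counts over a group's libraries was used, which covers counting error only. Intervals were taken over genes or loci as if these were independent, and they leave out the spread between libraries.

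On simulated counts with 200 changed genes, the procedure recovered 29% of 2-fold and 77% of 4-fold changes for the infection response in B728 (25344 genes tested) and called 3 unchanged genes. For the difference of the responses (25356 genes tested) it recovered 13% and 65% and called 9 unchanged genes. Apart from the changed genes, all simulated groups had the means of B728 control. In the simulation 109 genes were called for the response in B728, against 16413 in the real data. With so many genes passing, the adjustment lets larger p-values through, so these rates do not describe the reported tests. A simulated carry-over of 2% was estimated as 2.02%.

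Replicates were compared in pairs. The chi-square per degree of freedom over genes lay between 4.55 and 78.4, so no pair agreed within sampling noise. Each library was counted as 1 replicate, but this check cannot tell separate plants from repeats of 1 sample. The 3 pairs of C6 infected libraries lay between 4.55 and 6.49, and replicates 2 and 3 of B728 control at 6.29; the other pairs lay at 13.1 or above.

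Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter and a filter of 1 CPM in 3 libraries, fits on the libraries of a comparison alone, the replicate number as a block, each library left out, limma 3.58.1 on log2(FPKM + 1) or log2(FPKM + 0.1), and a minimum FPKM. Alternatives chosen after the data were seen were the score of a deviation shared by libraries of several groups as a covariate, fits without and within the 4 libraries that carry it, and C6 infected counts less the estimated B728 share. The deviation score is the first component of the within-group deviations of log2 CPM (61.2% of their variance) and the 4 libraries are those with a score over 0.1.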

Results

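Gene expression was measured by RNA sequencing in leaves of 2 inbred sunflower (Helianthus annuus) lines, with and without infection by Sclerotinia sclerotiorum, the necrotrophic fungus that causes white mould. B728 is the line labelled disease susceptible and C6 the line labelled disease resistant. Mock-inoculated controls and leaves collected 24 h after inoculation gave 4 groups of 3 libraries, 12 in all. The titles of the control samples give no collection time, so any difference in that time would be part of each infection response. The libraries held between 27758982 (B728 infected, replicate 1) and 36727715 counts (C6 control, replicate 2) over 27359 genes. The labels do not say whether replicates came from separate plants, so the p-values measure the spread between these libraries, which may be partly technical. With 1 line for each phenotype, a difference between the lines cannot be assigned to resistance. The first principal component of log2 CPM held 49.5% of the variance and the second 38.8%, and the 4 groups lay apart on them.

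**Figure D1:**
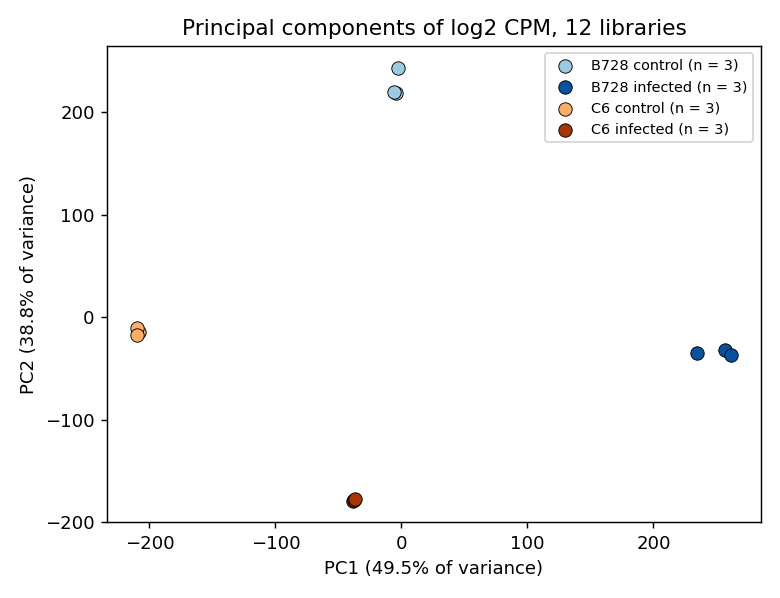
Principal components of log2 CPM (counts scaled to library size) for the 12 libraries, with the share of variance on each axis; each point is 1 library and the colour gives its group. The first component holds 49.5% and the second 38.8% of the variance, and the 3 libraries of each group lie together.

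Infection changed the leaf transcriptome of B728 on a wide scale. LOC110908638 rose from 2.26 ± 0.15 to 1551 ± 104 CPM (SD, n = 3), a log2 fold change of 9.42 ± 0.13 (SE). LOC110924489 rose from 1.30 ± 0.036 to 415 ± 21.2 CPM, by 8.32 ± 0.11 on the log2 scale. LOC110912864 fell from 1530 ± 106 to 35.9 ± 2.35 CPM, a log2 fold change of -5.42 ± 0.10, and LOC110865567 from 2148 ± 73.9 to 36.2 ± 4.96 CPM, a log2 fold change of -5.89 ± 0.12. All 4 are annotated as protein coding. Their adjusted p-values in edgeR's quasi-likelihood test were 5.62e-13 for both genes that rose, 1.76e-12 for LOC110912864 and 5.26e-12 for LOC110865567.

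Across the 27358 genes tested, 7823 were higher and 8590 lower in infected B728 at an adjusted p under 0.05, together 16413 genes. Of these, 5401 rose and 6089 fell by at least 2-fold. Changes over 16-fold were more often rises, with 1771 genes against 552 that fell. The genes that rose by at least 2-fold held 7.66% ± 0.43 of the counts in B728 control and 50.7% ± 0.99 in B728 infected libraries (SD, n = 3). The genes that fell by at least 2-fold went from 51.7% ± 1.15 to 11.5% ± 0.71 of the counts. These genes were picked on the B728 libraries, so their shares there are not independent of the calls. In C6, whose libraries entered the choice only through the scaling and the spread shared by the fit, the same genes that rose in B728 went from 9.20% ± 0.43 to 32.0% ± 0.068 of the counts, and those that fell in B728 from 47.8% ± 1.18 to 22.9% ± 0.015. The share of the calls that were rises was 47.7% with TMM scaling, 50.5% with RLE scaling and 37.4% with upper-quartile scaling, under which the median log2 fold change of all genes moved from -0.06 to -0.32. The deviations of replicate 1 of B728 control and replicates 1 and 3 of B728 infected from their group means correlated across genes with that of replicate 2 of C6 control. Without these 4 libraries 8962 genes were higher and 8550 lower in infected B728, where replicate 2 is then the lone infected library and is assumed to vary like the other groups. Within them, where B728 has 1 control library and the spread comes from the 2 B728 and 3 C6 infected libraries of that fit, 7729 were higher and 7566 lower.

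**Figure D2:**
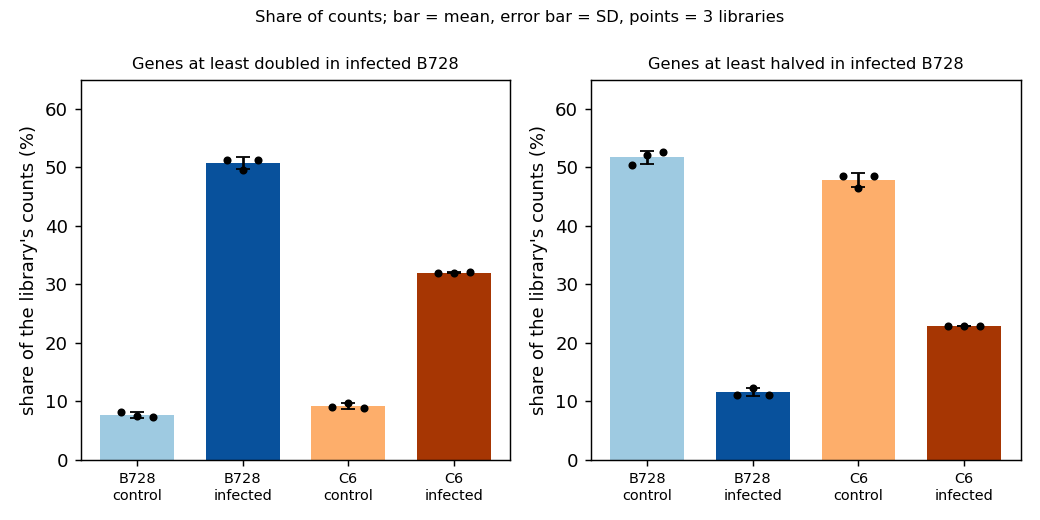
Share of each library's counts (%) held by genes that rose (left) or fell (right) by at least 2-fold in infected B728; bars are means, error bars SD and points the 3 libraries of a group. The genes that rose hold 7.66% in B728 control, 50.7% in B728 infected, 9.20% in C6 control and 32.0% in C6 infected libraries.

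Infection also changed the transcriptome of C6 on a wide scale. LOC110941651 rose from 0.48 ± 0.067 to 200 ± 5.28 CPM (SD, n = 3), a log2 fold change of 8.68 ± 0.12 (SE), and LOC110880086 from 25.7 ± 1.49 to 1678 ± 33.8 CPM, a log2 fold change of 6.03 ± 0.10. The 2 genes with the smallest adjusted p among those that fell were the same as in B728. LOC110912864 fell from 1537 ± 27.3 to 145 ± 5.15 CPM, a log2 fold change of -3.41 ± 0.09, and LOC110865567 from 1070 ± 18.3 to 65.5 ± 3.70 CPM, a log2 fold change of -4.03 ± 0.11. The edgeR adjusted p-values were 2.69e-12, 4.19e-12, 8.84e-11 and 1.28e-10.

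In total, 6561 genes were higher and 5444 lower in infected C6, 43.9% of those tested. With the libraries of each line fitted alone, 7575 genes were higher and 7192 lower in infected C6, and 7424 and 6558 in infected B728. Which line had more calls thus turned with the libraries fitted together. The joint fit shares 1 spread per gene over groups of unequal spread. The chi-square per degree of freedom of replicate pairs was 4.55 to 6.49 in C6 infected libraries. It reached 78.4 in B728 control, 72.9 in B728 infected and 66.2 in C6 control libraries. The cause of the turn was not tested. Rises made up 54.7% of the C6 calls with TMM, 54.8% with RLE and 46.1% with upper-quartile scaling, under which 5715 genes were higher and 6688 lower. By at least 2-fold, 4408 rose and 2944 fell, and 1329 rose and 140 fell by over 16-fold. Of the 1329 genes, 543 had 3 counts or fewer over the 3 C6 control libraries, so their fitted fold changes depend on the prior count. Loci read in B728 but not in C6 control had counts in the C6 infected libraries at about 1.79% ± 0.021 of their level in B728 infected libraries (SD over 3 libraries, 27 loci). From locus to locus the level ran from 0.87% to 3.49%, so a single share for all genes is an approximation. With the share estimated for each library subtracted, 6284 of the 6561 higher calls and 5358 of the 5444 lower calls were kept. Of the 1329 rises over 16-fold, 168 were lost.

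**Figure D3:**
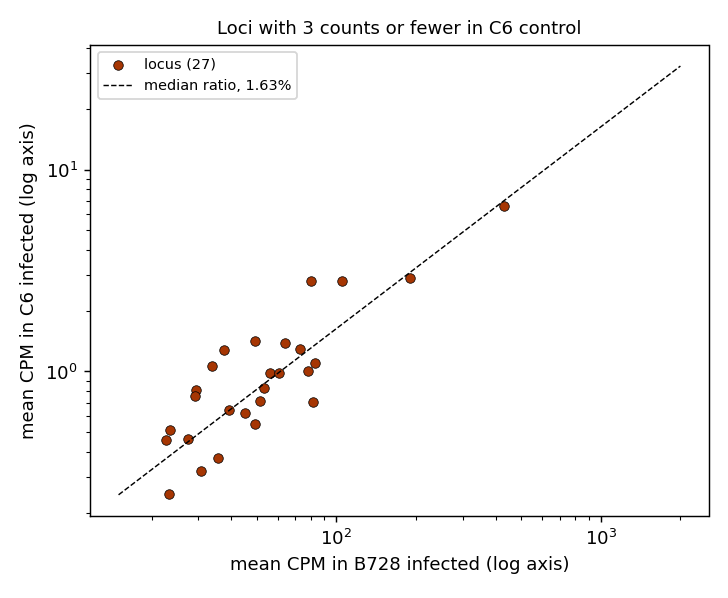
Mean CPM in C6 infected against B728 infected libraries, both on log axes, for the 27 loci with 3 counts or fewer over the 3 C6 control libraries and at least 20 CPM in both B728 groups; each point is 1 locus. All 27 were read in C6 infected libraries, at a median of 1.63% of the B728 infected level (dashed line).

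Most genes called in C6 were also called in B728 in the same direction, and most of the shared changes were smaller in C6. The lines shared 5281 higher genes, 80.5% of the C6 calls, where independent lists would share 1876. They shared 4430 lower genes, 81.4% of the C6 calls, against 1709 for independent lists. Among the shared genes the log2 fold change was larger in B728 for 78.6% of the higher and 80.1% of the lower genes, and the median ratio of the C6 to the B728 log2 fold change was 0.73 and 0.68. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.78 and a Spearman correlation of 0.73; the comparisons share no library. Opposite calls were fewer, with 119 genes higher in B728 and lower in C6 and 170 the other way, against 1557 and 2060 for independent lists.

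**Figure D4:**
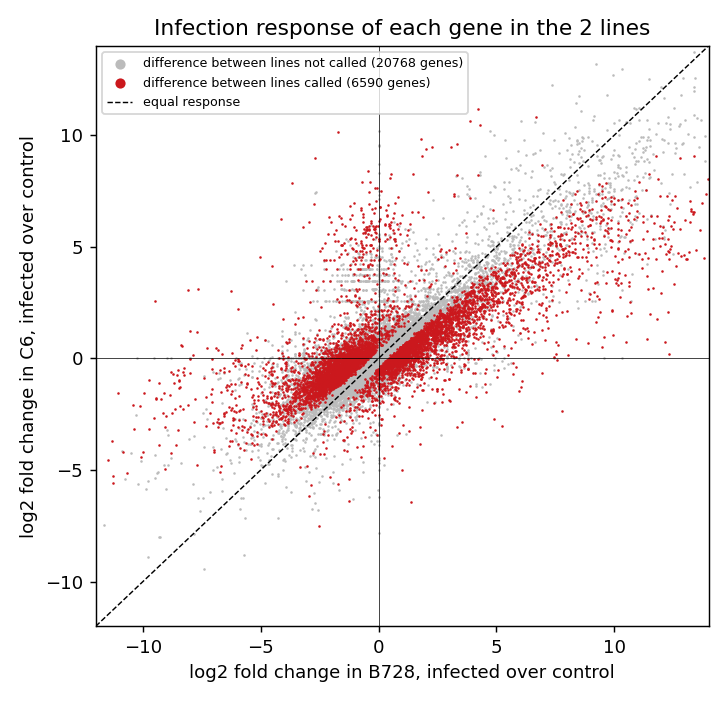
Log2 fold change of infected over control in C6 against B728 for the genes tested, within the axis range; red points are the 6590 genes whose responses differed between the lines and the dashed line marks equal response. Among shared calls 78.6% of the higher and 80.1% of the lower genes lie on the side of the larger B728 response.

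The study's design asks how the defence responses of the lines differ, and the difference of the infection responses (C6 minus B728) tests it gene by gene. LOC110941638 rose by 1.79 ± 0.20 in B728 and by 9.84 ± 0.34 in C6 (log2, SE), a difference of 8.05 ± 0.40. It started from 42.0 ± 4.19 CPM in B728 control and 0.093 ± 0.084 CPM in C6 control, and reached 145 ± 3.71 and 86.7 ± 3.80 CPM (SD, n = 3). The unannotated locus newGene_9644 changed in opposite directions, by -1.07 ± 0.09 in B728 and 1.56 ± 0.09 in C6. With the B728 share subtracted, its C6 change was 1.20. LOC110924489 and LOC110898214 rose more in B728, with differences of -3.57 ± 0.12 and -3.79 ± 0.14. In these 2 genes the lines differed before infection, since both were higher in C6 control (14.6 against 1.30 CPM and 11.5 against 1.53 CPM). The edgeR adjusted p-values of the differences were 2.11e-07 for LOC110941638, 2.03e-07 for newGene_9644, 4.84e-08 for LOC110924489 and 5.22e-08 for LOC110898214.

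The difference was positive for 3439 genes and negative for 3151; limma on log2(FPKM + 1) gave 6279 and 3217. Among the genes called in both lines in the same direction, the responses differed for 1981 of those that rose, 1853 of them with the smaller rise in C6, and for 1569 of those that fell, 1473 of them with the smaller fall in C6. Of the genes called in B728 and not in C6, 843 of the 2423 higher and 1303 of the 3990 lower genes differed between the lines by the test of the difference. Of those called in C6 and not in B728, 323 of the 1110 higher and 221 of the 895 lower genes did. These counts of genes called in 1 line hold for the joint fit of all 12 libraries. With each line fitted alone C6 had more calls, 7575 higher and 7192 lower against 7424 and 6558 in B728. Positive differences made up 52.2% of the calls with TMM, 47.0% with RLE and 63.2% with upper-quartile scaling. With the shared deviation of the 4 libraries as a covariate, a fit chosen after the data were seen, the counts were 5787 and 5092. That score was taken from the same counts and is centred within each group. It can lower the spread but cannot correct a shift between groups, so the larger counts are no support for the differences.

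Loci without a gene symbol, named newGene in the files, differed between the lines in direction. Of 4500 such loci tested, 553 rose and 1468 fell in B728, while 725 rose and 363 fell in C6. Their median log2 fold change in C6 was 0.04 with TMM, 0.04 with RLE and -0.02 with upper-quartile scaling, so the direction of the median depends on the scaling, although more of them were called higher than lower under each. With the B728 share subtracted, 596 rose and 365 fell in C6. The difference of the responses was positive for 735 and negative for 132 of these loci, and for 634 and 144 with that share subtracted. Falls in B728 also prevailed in 2 small annotated classes. Of 89 long non-coding RNA genes, 4 rose and 28 fell in B728, and 9 rose and 5 fell in C6. Of 45 genes of the class misc_RNA, 3 rose and 18 fell in B728, and 3 rose and 6 fell in C6. Of the protein-coding genes, 7109 rose and 6941 fell in B728, and 5683 rose and 4982 fell in C6.

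Without infection the lines already differed in the counts of 8127 genes, 4122 higher and 4005 lower in C6. Both lines were counted over the same genes, and whether their reads align equally well was not tested. LOC110924489 was higher in C6 control by 3.48 ± 0.09 and LOC110899723 by 5.25 ± 0.15 (log2, SE), the second at 46.7 ± 5.62 CPM against 1.22 ± 0.24 CPM in B728 control (SD, n = 3). LOC110899723 also rose in both lines after infection, by 6.29 ± 0.16 in B728 and 1.35 ± 0.12 in C6. newGene_9644 was lower in C6 control, with a log2 fold change of -6.64 ± 0.11, and so was LOC110941651, with -4.29 ± 0.11. The edgeR adjusted p-values were 1.18e-09, 1.31e-09, 1.54e-11 and 1.18e-09. Without the 4 libraries whose deviations correlated, 6819 genes were higher and 5059 lower in C6 control. Within them each line has 1 control library, so the 4338 higher and 3576 lower genes rest on the spread of the infected libraries.

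In the controls, 191 loci were read in C6 at 10 CPM or more with 3 counts or fewer over the 3 B728 libraries, and 190 loci in B728 with 3 counts or fewer over the 3 C6 libraries. Of these, 140 (73.3%) and 129 (67.9%) had no gene symbol, while such loci make up 16.5% of the files.

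After infection the counts of 14229 genes differed between the lines, 7049 higher and 7180 lower in C6, 52.0% of those tested. The limit on alignment given for the controls applies here too. The balance turned with the method. Upper-quartile scaling gave 8333 higher and 6041 lower genes. With limma on log2(FPKM + 1), to which no TMM scaling was applied, these were 11184 and 5112. newGene_16547 was at 412 ± 11.6 CPM in C6 infected and 0.20 ± 0.18 CPM in B728 infected libraries (SD, n = 3), a log2 fold change of 10.93 ± 0.33 (SE), and newGene_22301 differed by 4.81 ± 0.16. Both were also higher in C6 control, by 11.47 ± 0.33 and 5.59 ± 0.16. LOC110930121 was lower in C6 infected libraries, at 12.5 ± 0.90 against 280 ± 7.58 CPM, a log2 fold change of -4.49 ± 0.11, and newGene_9644 had a log2 fold change of -4.01 ± 0.10. The edgeR adjusted p-values were 2.58e-09, 4.45e-09, 6.24e-10 and 6.24e-10. LOC110924489 and LOC110908638, which differed between the controls, had log2 differences of -0.09 ± 0.08 and -0.18 ± 0.09 after infection, with edgeR adjusted p-values of 0.339 and 0.103. LOC110908638 passed the threshold in 4 of 25 alternatives, among them RLE scaling and DESeq2 (adjusted p from 0.00117 to 0.663 over all 25). LOC110924489 was higher in C6 by 0.22 with limma on log2(FPKM + 1) and passed there (adjusted p from 0.0217 to 0.828 over its alternatives).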

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

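Some of the tests below were chosen after their results had been seen. They are the 3 on loci read in B728 but not in C6 control and that on sample labels. The test on gene length over pairs of single libraries was also chosen then. Those on gene length over groups, scaling, the left-out libraries, dilution and regrouped libraries were written down before. For the left-out libraries this holds for the expected ratio only, since the fit without the 4 libraries was chosen after the data were seen.

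The response to infection differed between the lines by the test of the difference itself for 3439 genes with a more positive and 3151 with a more negative response in C6. Among the named genes the log2 differences (C6 minus B728) were 8.05 for LOC110941638, 2.63 for newGene_9644, 2.01 for LOC110912864, 1.86 for LOC110865567 and 1.73 for LOC110941651, which turned to -0.058 with limma on log2(FPKM + 1) (adjusted p from 1.35e-11 to 0.712 over the alternatives). They were -0.77 for newGene_22301, whose call was lost under 6 of 24 alternatives (adjusted p from 0.00722 to 0.154), -1.31 for LOC110880086, -1.56 for LOC110930121, -2.77 for LOC110908638, -3.57 for LOC110924489, -3.79 for LOC110898214 and -4.94 for LOC110899723.

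Regrouping the libraries tested how often other splits call as many genes. For each comparison of 3 against 3 libraries, 1 of 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 16413 and 38 for the response in B728, 12005 and 0 in C6, 8127 and 2 for the lines without infection, and 14229 and 0 after infection. For the difference of the responses, 6 of 60 splits drawn from 200, the real one included, called at least the real 6590 genes. All 5 others kept the B728 labels whole and so still held the response in B728, so their count does not measure chance. The highest of them, with 16953 genes, exchanged control and infected in C6 as a whole, which turns the difference of the responses into their sum; the other 4 exchanged 2 of 3 C6 libraries. In the 48 splits that mixed the labels within both lines, at most 8 genes were called. Groups that mix libraries from both sides of a comparison hold its difference in their spread, which lowers the calls. The low counts of these splits and of the 3 against 3 splits therefore do not measure false calls.

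Among shared calls the response in C6 was smaller than in B728. The scaling of the libraries is argued against as the cause, since the highest median ratio of the C6 to the B728 log2 fold change over TMM, RLE and upper-quartile scaling and both directions was 0.75. Without the 4 libraries that deviate together the higher of the 2 ratios was 0.69. A single share of unaffected tissue in the C6 samples was estimated as the complement of the 51.6% that the shared genes that rose give. It would leave the shared genes that fell at a median of -0.63, while -1.11 was observed. The median of observed less predicted was -0.52 (95% bootstrap interval over genes -0.53 to -0.50). Those genes had to be called in C6 too, and the share depends on that choice. For genes called in B728 by at least 2-fold, whatever their call in C6, it was 34.5%. The predicted and observed medians were then -0.41 and -0.89, and the median of observed less predicted -0.49 (interval -0.52 to -0.47). A share of affected tissue that differs between genes or cell types, a later time course in C6 and a smaller response per cell stay open, and the single time point tests none of them.

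Loci read in B728 but not in C6 control had counts in the 3 C6 infected libraries, for 27 of 27 loci at 20 CPM or more in both B728 groups. Their level followed that in B728 infected libraries (SD of the log2 ratio over loci 0.56) more closely than that in B728 control (1.47), which is consistent with about 1.79% of B728 infected RNA or reads in the C6 infected libraries. An exchange in both directions is argued against, since 63 loci read in C6 but not in B728 control had a median of 0% of their C6 infected level in B728 infected libraries. Induction of these loci in C6 cannot be told apart from carry-over by the test run, since 30 of 34 such loci that fell in infected B728 (88.2%) were read in C6 infected libraries, short of the 90% set as the bound. Of the 29 whose carried-over counts would exceed 3 times the floor, 27 were read (93.1%), and the exact Clopper-Pearson 95% interval of that share, 77.2% to 99.2%, holds the bound. Below the bound of 20 CPM a single share did not hold for all loci. LOC110935776 was at 11.7 CPM in B728 infected and 4.69 CPM in C6 infected libraries. The locus newGene_18929 was at 13.7 CPM in B728 infected libraries and had 0 counts in C6 infected libraries. With the estimated share subtracted, 277 higher and 86 lower calls in C6 were lost and others gained, which left 6312 higher and 5402 lower.

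Replicate 1 of B728 control, replicates 1 and 3 of B728 infected and replicate 2 of C6 control deviated together from their group means. Across 14290 genes, which are not independent replicates, the deviations of these libraries in different groups correlated at 0.45 to 0.69 (5 pairs). The 4 libraries were picked by their score on the first component of the same deviations, so positive correlations among them follow from the choice. The rest of these 3 groups' libraries also correlated across groups, at 0.26 to 0.63. Deviations cancel within a group, so the 2 ranges are not independent, and the libraries form 2 sets. A wrong label is argued against, since 0 of the 4 libraries had the highest rank correlation with another group. Gene length is argued against as the whole cause, since the mean correlation over these 5 pairs was 0.53 before and 0.51 after the trend with length was removed, and that between the 3 groups' contrasts of these libraries with the rest of their group 0.71 and 0.69. In B728 infected that contrast is the deviation of replicate 2 with its sign turned, so replicate 2 could equally be the library apart. A batch of library preparation, sequencing or harvest stays open; the labels give none, and no biological explanation was tested. The C6 infected libraries did not deviate from one another in this way (scores from -0.0039 to 0.0037), so they could not be placed.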

How the results depend on the processing

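The fits on the deviation score, without or within the 4 libraries that deviate together, and on counts less the B728 share were chosen after the data were seen. Of 304 counts of calls recomputed under an alternative, 292 stayed within 1.5 times the reported count. With limma on log2(FPKM + 1), with or without the FPKM minimum, which removed 0 genes, 6279 genes had a positive difference of the responses and 11184 were higher in C6 after infection; with log2(FPKM + 0.1) these were 5804 and 11018, and 4770 were lower. With the deviation score as a covariate, 5787 differences were positive and 5092 negative. The score is centred within each group, so this fit can lower the spread but corrects no shift between groups. Without the 4 libraries, 6819 genes were higher in C6 control; B728 infected then keeps 1 library, and within the 4 each line has 1 control library, lone libraries being assumed to vary like the other groups. At an adjusted p under 0.01 with at least 2-fold change, 3192 higher and 2009 lower genes were shared, as a stricter threshold must give fewer. No TMM scaling was applied to the FPKM values. The mean TMM factor was 1.09 in C6 infected and 0.886 in B728 infected libraries, and 1.05 and 0.984 in the controls. Leaving it out raises C6 infected values relative to B728 infected ones, the direction of the FPKM shifts. How much of those shifts it gives was not tested, nor was the cause of the other shifts. Of 1637 values of named genes, 60 changed their call, 45 lost, 13 gained and 2 with the sign turned; the difference of the responses of LOC110941651 turned from 1.73 to -0.058 (limma adjusted p = 0.712) with log2(FPKM + 1), a scale that understates changes of low genes. Calls of newGene_22301, newGene_16547 and LOC110930121 (in C6, with the B728 share subtracted) after infection, the difference of the responses of newGene_22301, LOC110880086 without infection and LOC110899723 and LOC110941638 between infected lines were lost under at least 1 alternative. Calls of LOC110908638 and LOC110924489 between infected lines, newGene_22301 in C6, the difference of the responses of newGene_16547 and LOC110912864 without infection were gained under at least 1 alternative. Leaving out each library in turn gave 2453 to 4845 positive and 2523 to 3854 negative differences, 7225 to 8239 higher and 7746 to 8755 lower genes in B728, and 5770 to 7000 and 4308 to 5929 in C6; where an arm kept fewer libraries, its spread was taken from the other groups. The replicate numbers did not pair the samples: deviations of control and infected libraries with the same number in 1 line correlated from -0.41 to 0.59 (2 of 6 over 0.1), and 3 of 12 libraries correlated best with their own number. With the replicate block, 2844 differences were positive and 2689 negative, and 7543 higher and 8203 lower genes were called in B728. The gene list alternatives were not run because no list could be filled. The fit on a comparison's own libraries is the reported fit for the difference of the responses.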

Other observations

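The tests on neighbouring genes were chosen after the pattern had been seen, and the second form of the simulation on uninfected levels after its first form.

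Genes that responded alike lay next to each other more often than shuffled calls would. Among 8851 pairs of tested genes that are adjacent on the assembly HanXRQr2.0, an order that may differ from that of the authors' build, both rose by at least 2-fold in B728 in 537 pairs, against a mean of 412 and a maximum of 474 in 1000 shuffles. In C6 there were 345 such pairs, against a mean of 245 and a maximum of 297. For genes that fell, the counts were 498 against a mean of 415 in B728 and 167 against 127 in C6. The permutation p was 0.001 in all 4 cases, the smallest that 1000 shuffles can give. A candidate explanation is that clusters of related genes respond together; near-identical neighbours that share reads could give the same pattern, and that was not tested.

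A second hypothesis was that genes with a strong rise in B728 start higher in uninfected C6, as LOC110924489 and LOC110899723 did. Of the 1771 genes that rose over 16-fold in B728, 600 were higher and 125 lower in C6 control, an excess of 475. B728 control enters both comparisons, and genes with few counts there have little room to be lower in C6. The line differences were therefore shuffled among genes of similar B728 control level in 20 simulated data sets. The simulation was run in 2 forms. The first, with no floor on the ratios, gave an excess of 644 to 735; the second, with a floor of a fraction of 1 count per library set after the first was seen, gave 671 to 768. The observed excess lay below both ranges, so the predicted result was not seen in either form. Yet every gene in the files had an FPKM of at least 1 in at least 3 libraries. A gene low in B728 control was therefore kept through another group, which can be C6 control. The shuffle can pass such line differences to the strongly rising genes and raise the simulated excess. The simulation thus cannot decide the hypothesis.

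All 3 pairs of C6 infected libraries had a chi-square per degree of freedom of at most 6.49, while each other group had a pair at 66.2 or above. In those groups the pairs at 48.5 or above all joined 1 of the 4 libraries that deviate together with a library outside them. The remaining pair lay at 6.29 in B728 control, 15.0 in B728 infected and 13.1 in C6 control libraries. Most of the contrast with C6 infected libraries thus goes with that shared deviation. The C6 infected libraries had 702 to 715 genes at 0 counts, against 1172 to 2215 in the other 9 libraries. Of those 9, the 4 libraries that deviate together had 1665 to 2215 and the rest 1172 to 1496. Signal carried over from B728 into the C6 infected libraries would lower their number of genes at 0. That number was 876 to 891 with the estimated B728 share of 1.79% subtracted, a test chosen after the data were seen. In the C6 infected libraries 50% of the counts were held by 1517 to 1544 genes, against 804 to 1149 in the others.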
